A study of Mus musculus with 8 samples.

How the data were processed

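The data came from the cerebral cortex of male mice aged 6 weeks, wild type (WT) or lacking Fmr1 (KO), the gene of the RNA-binding protein FMRP. RNA of 6 mice was pooled for each biological replicate, and each genotype had 2 pools. From each pool 1 library was made from RNA enriched with an antibody against N6-methyladenosine (m6A-IP) and 1 from RNA without enrichment (non-IP), which gave 8 libraries. The submitters' processing notes name Bowtie2 2.2.4, HOMER, Cufflinks 2.2.1, Cuffdiff 2.2.1 and the mouse build mm9. The role and order of these tools were not given in the sources used here, and neither was the annotation.

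Gene and isoform levels were deposited as FPKM by the authors, with 1 pooled value per genotype, so no spread between pools and no n can be attached to a level. The p-value and q-value of each gene and isoform were deposited by the authors from Cuffdiff, per the file headers and file names, and the smallest p-value in either table was 5e-05. Peak lists of 1 table per genotype were deposited by the authors with a fold enrichment ratio, a peak p-value and the log10 of the p-value and FDR, per the file headers. The name MeTPeak for these lists, and MeTDiff for the table of differential sites, is known from the names under which they were deposited. The differential table holds, per the file headers, a deposited log2 fold change in methylation of KO against WT for each site. Its log10 p and FDR of the difference were used as deposited by the authors, although 1 value lies far outside the range of the others. HOMER peak lists were deposited by the authors for each m6A-IP library, with the count of tags in a peak, the normalized tag signal, the fold over a control library, a p-value and HOMER's own score, per the file headers. The control library is not identified in the sources used here. Other deposited columns, such as peak width and block sizes, served for positions. Folds and scores of a peak are the authors' own, and were used to describe, rank or filter peaks within a list.

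The totals behind each HOMER list were recovered from its scaling. The list gives tags both as counted and scaled to 10 M tags (M, mega), which gives 1 of the library totals, and the step between low scaled values gives the other. Between 84.5% and 100% of low values came out as whole tags within 0.1 tags. Every HOMER peak is listed on the plus strand, so strand was not used in overlaps with HOMER peaks. MeTPeak peaks were compared block by block on the same strand. A shared peak had at least 1 base in common. The overlap routine was written in Python, and its counts were equal to those of bedtools 2.31.1 in 22 of 22 comparisons. A peak of 1 genotype was called replicate-backed where no MeTPeak peak of the other genotype overlapped it, both HOMER lists of its own genotype did, and neither of the other genotype did. A gene with an m6A peak in both genotypes is called m6A-marked. Where HOMER peaks defined the genes, a gene counted for a library if its HOMER peaks overlapped a MeTPeak peak of the gene in either genotype.

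Expression calls used the deposited q-value at 0.05, and methylation calls the deposited FDR at 0.05. The expression and differential methylation tables hold no values per library, so their deposited tests were used, and the tags per library in the HOMER lists served to describe the libraries and, in the closing section, to test whether a single library set a pattern. Log2 changes were computed here as log2((FPKM in KO + 1)/(FPKM in WT + 1)), a scale that understates the change of low genes. The deposited log2 fold change of expression was not used, since its column holds text where KO is at 0. Genes at 0 FPKM in a genotype are said to be listed at 0, with no fold. Gene groups were compared over genes with a mean of at least 1 FPKM. A list's median log2 change was placed among the medians of 10000 random lists of the same size, drawn with replacement from genes outside the list in 20 bins of mean FPKM, and is called outside their range below the 2.5 or above the 97.5 percentile. m6A-marked genes were compared with genes that had no peak in either genotype. Genes are not replicates, so these percentiles describe the deposited values and are not p-values between animals. Overlaps were tested with Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over the 25 lists.

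The lists, fixed before the data were examined, were m6A machinery, transcripts bound by FMRP in brain (from general knowledge of cross-linking studies), glutamate receptors and postsynaptic scaffolds, GABA signalling, interneuron markers, excitatory neuron markers, immediate early genes, and markers of astrocytes, oligodendrocytes and myelin, oligodendrocyte precursors, microglia, blood vessels, meninges, choroid plexus, red cells, striatum, hippocampus, and thalamus and hypothalamus. The others were ribosomal proteins, oxidative phosphorylation, mTOR signalling and translation, ion channels, cytoskeleton and axon guidance, chromatin regulators, and interferon and inflammation genes. The groups, tests and alternatives were fixed at the same time, apart from those named below as chosen later or as not fixed beforehand. Named genes followed a rule fixed then: Fmr1 first, the 12 largest rises and 12 largest falls among genes called at 1 FPKM or more in the higher genotype, the called methylation sites (12 at most each way), the 8 replicate-backed peaks of highest fold per genotype, the 6 highest-fold WT peaks among genes at 5 FPKM or more, up to 4 members of each list by smallest q, and up to 10 genes called in both tables. Genes named outside the rule are marked as such, and some genes that the rule takes are not reported here.

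The percentile method was tested on simulated changes for 12971 genes with a trend over expression level. Lists of 20 genes shifted by -0.5 on the log2 scale were called in 97.5% of 40 simulated lists, lists shifted by 0.3 in 77.5%, and unshifted lists in 0%. Without matching, 7.5% of unshifted lists were called high. Simulated genes varied independently and had no trend over locus span, so these rates do not hold for lists of genes that change together or differ in span. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and SciPy 1.17.1, and figures matplotlib 3.10.9. Positions are in mm9 as the files give them, written 1-based. Positions along transcripts, sequence motifs and transcript lengths were not analysed here, because no genome or annotation of that build was used.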

Results

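Cortical RNA of WT and Fmr1 KO mice was profiled with and without enrichment for N6-methyladenosine (m6A), a modified base of mRNA that is recognised by reader proteins. Each genotype was represented by 2 pools of 6 mice. The title of the series names the question: whether FMRP changes the stability of those of its mRNA targets that carry m6A. The deposited tables hold levels at a single time point, so they show abundance and not decay. The m6A-IP libraries behind the peak lists held 16.4 and 17.5 M tags (M, mega) in WT replicates 1 and 2, and 21.2 and 19.5 M tags in KO replicates 1 and 2. Their control libraries were less even, with 19.2, 12.9, 24.9 and 8.24 M tags in the same order. Depth per library behind the FPKM values is unknown. Gene levels were given for 23951 genes, of which 12971 had a mean of at least 1 FPKM.

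**Figure D1:**
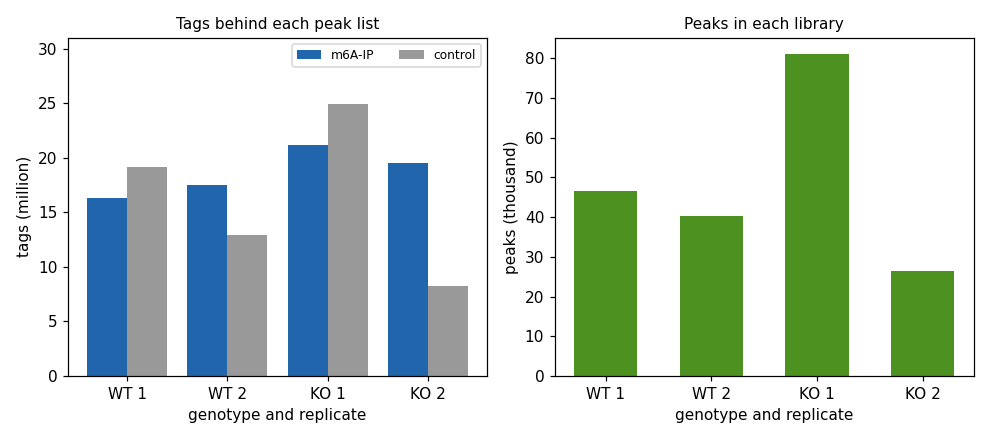
Tags behind each HOMER peak list (left, in M tags, m6A-IP and control library) and the number of peaks in the list (right, axis in units of k) for the 4 m6A-IP libraries, 1 bar per library. KO replicate 1 had the largest control library, 24.9 M tags, and the longest list, 81134 peaks, and KO replicate 2 had the smallest, 8.24 M tags, and the shortest, 26368.

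The peak lists of the KO libraries differed in length more than those of the WT libraries. HOMER listed 46573 and 40212 peaks in the WT replicates, and 81134 and 26368 in the KO replicates. Of the peaks of KO replicate 1, 54.4% lay in a gene locus of the expression table, and 37023 lay outside, against 84.0%, 88.5% and 85.0% in loci for WT replicate 1, WT replicate 2 and KO replicate 2. A set of 14685 peaks of WT replicate 1, 31.5% of its list, was overlapped in every other library. The Jaccard index in bases was 0.220 between the WT replicates, 0.176 between the KO replicates, and from 0.151 to 0.266 between genotypes. By this index, which depends on list length, pairs within a genotype were no more alike than pairs between genotypes, with means of 0.198 and 0.207 (difference -0.00893, highest other split 0.00702, one-sided exact permutation of the genotype labels, p = 1, 3 of 3 splits as large). With 2 libraries per genotype the 3 splits cannot give a p below 1 in 3, and without KO replicate 2 the difference turned to 0.0691. With equal numbers of peaks it was 0.00382, and by the shared percent of the smaller list pairs within a genotype were more alike by 4.26 percentage points, a value of -1.16 with equal numbers of peaks, -15.8 without KO replicate 1, 16.1 without WT replicate 1, 15.3 without WT replicate 2 and 1.43 without KO replicate 2.

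Most genes with an m6A peak in WT cortex also had one in KO cortex. The MeTPeak lists, 1 per genotype, held 7089 peaks in 4179 genes in WT and 10212 peaks in 5601 genes in KO. Both lists shared 3866 genes, 313 had a peak in WT alone and 1735 in KO alone. The genes with most peaks were the presynaptic scaffold genes Pclo, with 21 peaks in WT and 22 in KO, and Bsn, with 13 in each. Plec, which codes for a cytoskeletal linker, had 11 and 13 peaks. Map1a and Map1b, which code for microtubule-associated proteins, had 11 and 10, and 9 and 9 peaks. The histone methyltransferase gene Kmt2d had 10 and 9, Arhgap35 10 and 7, and Apc, a regulator of Wnt signalling, 9 and 11. These genes were chosen by peak number after the values were seen. Fmr1 itself had no peak in either list. The highest fold enrichments in WT among genes at 5 FPKM or more were the authors' values of 1850 in 2900097C17Rik, 350 in Gapdh, 283 in Hspa8, 270 in Stmn1, 217 in Hnrnpa3 and 213 in Ube2v1. The median fold of all WT peaks was 7. Read counts behind these high ratios were not examined, so the ratios do not rank the amount of m6A.

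Of the WT peaks, 88.8% were overlapped by a KO peak, and of the KO peaks, 59.9% by a WT peak. The 4097 KO peaks with no WT counterpart in MeTPeak were nonetheless overlapped by HOMER peaks of WT replicate 1 in 76.2% and of WT replicate 2 in 76.2% of cases, close to the 81.2% and 78.6% in KO replicates 1 and 2. For the 792 WT peaks with no KO counterpart the shares were 79.7% and 72.3% in the WT libraries and 52.8% and 45.8% in the KO libraries. Peaks backed by both libraries of 1 genotype and by none of the other numbered 84 in WT and 82 in KO. Without WT replicate 1 the KO number was 427, without WT replicate 2 it was 369, without KO replicate 1 it was 131 and without KO replicate 2 it was 148. The WT number was 154, 169, 177 and 133 in the same order. Examples in WT were peaks in Ywhah, which codes for a 14-3-3 protein (chromosome 5, 33369685 to 33369831), Dmwd, Nap1l3, Arhgap35, Rnf165, Tanc2, Rif1 and Ankrd13d, with the authors' fold enrichments from 8.76 to 5.83. Examples in KO were peaks in Lats2, a kinase of the Hippo pathway (chromosome 14, 58310333 to 58310433, fold 13.7), the chromatin remodeller gene Arid1a (fold 9.74), Mfsd9, Cebpa, Asnsd1, Fut8 and 2610524H06Rik. No p-value is given for these counts, which have no replicate error.

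Few sites were called as different in methylation between the genotypes. In the authors' deposited table of 10305 sites in 5990 genes, 12 sites passed FDR 0.05, of which 10 were higher and 2 lower in KO (83.3% higher, exact 95% binomial interval 51.6% to 97.9%, counting error only). At an unadjusted p of 0.05 or less, 817 sites were higher and 487 lower, 1304 in all, where 515 were expected by chance. With this excess and 2 pools per genotype, the 12 calls do not show that other sites were unchanged. The largest called rises in the authors' deposited table were in Akap6, a kinase-anchoring protein gene (log2 change 2.29, FDR 0.0468, chromosome 12, 54249013 to 54249113), and Derl1, of endoplasmic reticulum quality control (2.14, FDR 0.0468). Polr2a, the largest subunit of RNA polymerase II (chromosome 11, 69548050 to 69548897), rose by 1.76 in the authors' deposited table, with an FDR far outside the range of all other sites. Other rises in the authors' deposited table were 1.63 in Gsg1l, 1.35 in Cpped1, 0.51 in Ankrd12, 0.49 in Sept6, 0.41 in Rnf103 and 0.41 in Sdhaf2. The falls in the authors' deposited table were -1.96 in 4930470H14Rik, which was listed at 0 FPKM in both genotypes, and -0.38 in Dido1 (FDR 0.0182). The sites in Gsg1l and 4930470H14Rik were overlapped by no HOMER peak in any library, and those in Dido1, Cpped1, Rnf103, Sdhaf2, Sept6 and Ankrd12 by 1 in all 4. The Sept6 site, listed as higher in KO, was overlapped by a MeTPeak peak in WT alone, and those in Polr2a, Cpped1, Akap6, Derl1 and Gsg1l by 1 in KO alone. Over 6019 sites with a MeTPeak peak in both genotypes, the sign of the deposited change was that of the log2 ratio of peak folds in 73.9%.

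Fmr1 fell from 15.3 FPKM in WT to 3.48 FPKM in KO, 22.8% of the WT level (q = 0.00113 in the authors' deposited table). Its isoform NM_008031 fell from 10.2 to 2.87 FPKM (q = 0.00158), and NM_001290424, at 5.11 and 0.616 FPKM, was not called (q = 0.476) in the authors' deposited table. The remaining reads do not show whether a complete transcript was made.

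Expression differed between the genotypes in both directions, with ribosomal, respiratory chain and striatal genes higher and ion channel, chromatin and FMRP-bound genes lower in KO. The authors' deposited table called 952 genes higher and 1083 lower among 12871 tested, and 791 isoforms higher and 894 lower among 16259. Of 1675 genes with a called isoform, 1603 were also called as genes. Among the called genes, 157 rose and 321 fell by over 2-fold, without a pseudocount. The median log2 change of all genes at 1 FPKM was 0.02. The p-values rest on 2 pools per genotype, and the spread between pools is not in the table.

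The genes with the largest rises included markers of the striatum and of vessels. Adora2a, an adenosine receptor gene of striatal neurons, rose from 7.74 to 25.4 FPKM, and Penk, which codes for proenkephalin, from 72.8 to 234 FPKM (q = 0.00113 for each in the authors' deposited table). Mgp, a matrix protein gene, rose from 7.83 to 25.6 FPKM, Myl9, of smooth muscle, from 4.18 to 13.0, Hspb1, a small heat shock protein gene, from 1.88 to 6.20, and Emcn, of endothelium, from 0.945 to 3.32. Further rises were those of Dlk1, from 0.518 to 2.01 FPKM, Lsm12, from 5.23 to 16.4, A930005H10Rik, 3.11-fold from 3.21, and the transcription factor gene Zfp503, from 0.759 to 2.36. Apoc1 was listed at 0 in WT and at 3.07 FPKM in KO. The q-values of these genes in the authors' deposited table ran up to 0.0370.

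The largest falls were of small noncoding RNAs, histone genes and the NMDA receptor subunit gene Grin2b. Grin2b fell from 45.0 to 6.88 FPKM, a log2 change of -2.54 with the pseudocount (q = 0.00113 in the authors' deposited table). Rmrp, the RNA of RNase MRP, fell from 665 to 46.3 FPKM, and Rpph1, the RNA of RNase P, from 357 to 58.7. AB041803 fell from 8.38 to 0.864 FPKM, the potassium channel subunit gene Kcng3 from 2.79 to 0.335, and 9530059O14Rik from 1.57 to 0.234. The histone genes Hist1h4f and Hist1h4c, at 4.28 and 3.86 FPKM in WT, were listed at 0 in KO, as were Ctsg, Ereg, Olfr447 and Sult1e1, at 2.5, 1.76, 1.73 and 1.47 FPKM in WT. Histone genes belong to families of near-identical copies, so their levels depend on how shared reads were assigned.

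Genes of the striatum, the region beneath the cortex, rose together. Of 14 expressed striatal markers 12 rose, none fell and 2 were not called (12 adjusted over the list alone), with a median log2 change of 0.96, above all 10000 random lists. Besides Adora2a and Penk, the dopamine receptor gene Drd1a rose from 3.42 to 9.28 FPKM and Pdyn, which codes for prodynorphin, from 5.89 to 15.4. Of 47 ribosomal protein genes 40 rose and none fell (40 adjusted over the list alone), with a median of 0.79, above every random list. Random lists were themselves raised, with a median of 0.29 when matched on level and 0.45 on level and locus span, so the list lay higher by 0.50 and by 0.34. Rpl38 rose from 451 to 1215 FPKM, Rps4x from 71.4 to 185 and Rpl10 from 55.5 to 129, although ribosomal protein genes have many pseudogene copies that can share reads. Of 38 genes of oxidative phosphorylation 24 rose and none fell (33 adjusted over the list alone, median 0.62, higher than random lists by 0.34 with matching on level and by 0.28 on level and locus span), among them Cox5a, from 70.3 to 147 FPKM, Ndufb5, from 33.0 to 65.8, Uqcrfs1, from 36.1 to 71.5, and Atp5o, from 91.1 to 180. Of 15 microglia markers 5 rose and none fell (5 adjusted over the list alone, median 0.34, percentile 99.3), with Ctss from 22.6 to 45.3 FPKM, Fcrls from 8.75 to 15.2, Csf1r from 22.5 to 33.3 and C1qc from 22.4 to 34.5. Of 19 vessel markers Bsg, from 167 to 299 FPKM, and Myl9 rose (2 adjusted over the list alone, median 0.30, percentile 99.7). The call of the microglia list was not made with lists matched on level and locus span (percentile 96.8), and that of the vessel list was not made among genes at 5 FPKM or more.

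Genes for ion channels and chromatin regulators fell. Of 33 channel genes 17 fell and 1 rose (18 and 1 adjusted over the list alone), with a median of -0.56, below every random list. Kcnh7 fell from 12.4 to 4.28 FPKM, Kcnq3 from 23.0 to 9.42, Kcnma1 from 31.5 to 12.9 and Kcnd3 from 17.1 to 7.36. Of 33 chromatin regulators 17 fell and none rose (22 adjusted over the list alone), with a median of -0.51, below every random list, and the histone methyltransferase genes Kmt2a, from 21.6 to 10.7 FPKM, Kmt2c, from 9.43 to 4.50, and Dot1l, from 51.7 to 27.9, and the remodeller gene Chd2, from 14.7 to 7.88, were among them. Of 37 glutamate receptor and scaffold genes 9 fell and none rose (9 adjusted over the list alone, median -0.22, below every random list, or at percentile 2.25 with matching on locus span), including Grin2b, Grin2a, from 27.3 to 8.40 FPKM, Shank1, from 269 to 125, and Homer2, from 8.70 to 4.53. Of 40 cytoskeleton and axon genes 5 fell and 4 rose (6 and 4 adjusted over the list alone, median -0.27, below every random list). Map1b fell from 128 to 63.8 FPKM and Plxna4 from 14.0 to 8.11, whereas Gap43 rose from 100 to 170 and Tubb3 from 166 to 260. Of 14 excitatory neuron markers 2 fell, Rorb, from 5.31 to 3.43 FPKM, and Rasgrf2, from 25.3 to 17.3 (2 adjusted over the list alone, median -0.23, percentile 1.86, or 6.33 with matching on locus span). In peak windows found in every library, control tags of the channel genes were lower in KO by a median log2 difference of -0.42, or -0.12 without WT replicate 2, although of the 4 differences between single libraries that of KO replicate 2 from WT replicate 1 was 0.04 (the others -0.32, -0.42 and -0.68). Those of chromatin regulators were lower by -0.40, or -0.22 without WT replicate 2 (single differences from -0.60 to -0.11). Those of glutamate receptor and scaffold genes were lower by -0.10, or -0.02 without KO replicate 1 and -0.21 without WT replicate 1 (single differences from -0.26 to -0.07). The FMRP-bound list holds 12 of the cytoskeleton, 11 of the glutamate, 9 of the chromatin and 8 of the channel genes. Without them 1 of 28 cytoskeleton genes fell and 4 rose (median -0.17, percentile 0.44), and 5 of 26 glutamate, 11 of 24 chromatin and 12 of 25 channel genes fell. Nuclear noncoding RNAs, a list chosen after the data were seen, were lower in the same tables, with 6 of 11 falling, none rising and a median of -0.70. The ribosomal protein and oxidative phosphorylation genes and the striatal, vessel and microglia markers moved in the same tables and in the opposite direction to these groups and RNAs.

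**Figure D2:**
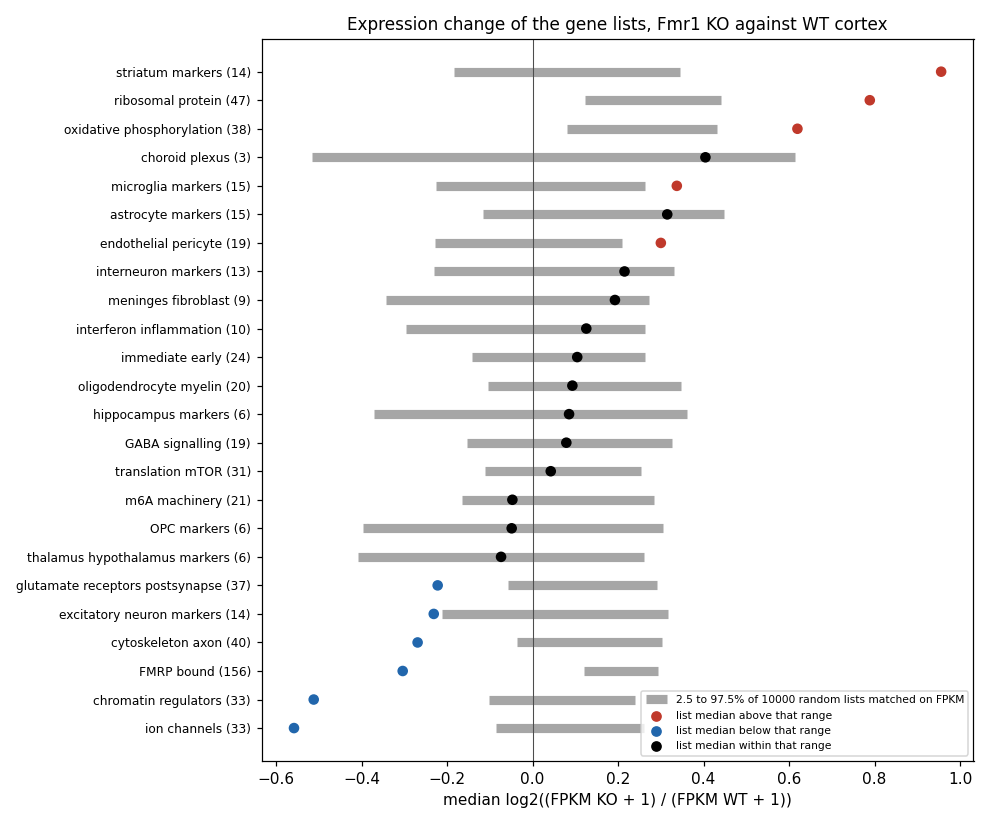
Median log2((FPKM in KO + 1)/(FPKM in WT + 1)) of each gene list with at least 3 expressed genes (points, number of genes in parentheses) and the central 95% range of 10000 random lists matched on FPKM (grey bars). Striatal markers, at 0.96, and ribosomal proteins, at 0.79, lie above their ranges, and ion channels, at -0.56, and chromatin regulators, at -0.51, lie below.

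Apart from FMRP-bound transcripts, the other lists stayed within the range of random lists, save the red cell list, which had 2 expressed genes, Hbb-bt at 3.61 and 6.01 FPKM and Hbb-bs at 0.0226 and 19.8 FPKM in WT and KO, neither of them called (median 2.48, percentile 100). Of 21 expressed genes of the m6A machinery 2 fell, the writer complex members Rbm15, from 6.26 to 2.53 FPKM, and Zc3h13, from 38.9 to 19.9, and none rose (2 adjusted over the list alone, median -0.05). In GABA signalling Slc32a1, the vesicular transporter gene, rose from 38.8 to 63.3 FPKM, Gabrd rose from 27.9 to 41.9 and Gabrb1 fell from 9.20 to 4.78 (4 higher and 1 lower adjusted over the list alone, median 0.08 over 19 genes). In mTOR signalling and translation 3 of 31 genes rose and 2 fell (4 and 2 adjusted over the list alone, median 0.04), with Eef1a1 from 442 to 894 FPKM and Eif2ak4 from 11.7 to 6.30. Dusp6 and Fos rose among 24 immediate early genes (0 adjusted over the list alone, median 0.10), Gjb6 and Aldoc among 15 astrocyte markers (2, median 0.31), Trf and Mog among 20 oligodendrocyte genes (1, median 0.09), and Ptgds and Col1a1 among 9 meningeal markers (2, median 0.19). Ttr rose from 62.9 to 129 FPKM among 3 expressed choroid plexus markers (1, median 0.40), and Ifitm3 rose among 10 interferon and inflammation genes (0, median 0.13). Dlx1 fell among 13 interneuron markers (1, median 0.22), Rora among 6 thalamic and hypothalamic markers (1, median -0.07), and Zbtb20 fell and Calb1 rose among 6 hippocampal markers (1 each, median 0.09). None of 6 oligodendrocyte precursor markers was called (median -0.05). The counts in parentheses without further words are adjusted over the list alone.

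The lists differed in how often their genes had an m6A peak, in comparisons not matched on level or locus span. In WT, 81.8% of the expressed ion channel genes, 79.2% of immediate early genes, 78.8% of chromatin regulators, 75.7% of glutamate receptor and scaffold genes, 67.5% of cytoskeleton and axon genes and 64.3% of excitatory neuron markers had a peak, against 31.7% to 31.8% of other genes (Fisher's exact test, adjusted p from 5.66e-08 for the channels to 0.0481 for the neuron markers). Ribosomal protein genes had a peak in 8.51% (adjusted p = 0.000726) and oxidative phosphorylation genes in 2.63% of cases (adjusted p = 4.49e-05, Fisher's exact test). The other 16 lists, FMRP-bound transcripts aside, did not pass the test. With the KO peaks the cytoskeleton genes (adjusted p = 0.0783) and the neuron markers (adjusted p = 0.273) did not pass, and with HOMER peaks in both WT libraries the neuron markers did not (adjusted p = 0.157, Fisher's exact test). The HOMER version counted only genes with a MeTPeak peak in either genotype, so it is not a check apart from MeTPeak.

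m6A-marked genes were lower in KO than genes without a peak. Of 3829 marked genes at 1 FPKM, 481 fell and 170 rose, and of 7189 genes with no peak, 449 fell and 666 rose. The share of falls among called genes was 73.9% in marked and 40.3% in unmarked genes (odds ratio 4.20, Fisher's exact test across genes, which are not independent, p = 1.43e-43). This test was not among those fixed beforehand and was not matched on level or locus span. The median log2 change was -0.04 in marked and 0.06 in unmarked genes. Unmarked genes matched on level had a median of 0.12 (range of 95% of random lists 0.104 to 0.136), so the marked genes were lower by -0.16, below every random list. Of 1953 genes with a peak in 1 genotype 139 fell and 116 rose, with a median of 0.05, within the range of random lists (percentile 31). Those with a peak in WT alone had a median of -0.07 (303 genes, 65 falling and 21 rising, below every random list) and those with a peak in KO alone 0.07 (1650 genes, 74 falling and 95 rising, percentile 99.7).

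Transcripts bound by FMRP, a list taken from general knowledge of cross-linking studies, had an m6A peak more often and were lower in KO. Of 156 such genes 95 were m6A-marked, 60.9%, against 29.1% of other genes (odds ratio 3.79, Fisher's exact test, p = 4.65e-16). This comparison was not matched, and FMRP-bound genes had medians of 55.9 FPKM and 93.6 kb of locus span, against 10.1 FPKM and 26.5 kb in all genes. The share of marked genes was 24.6% in the shortest of 10 groups by locus span and 40.3% in the longest. Whether level and span account for the difference was not tested. Of the 156 genes 56 fell and 7 rose (60 and 11 adjusted over the list alone), with a median of -0.30, below every random list. Of the 95 that were m6A-marked, 44 fell and 1 rose, with a median of -0.43, and of the 51 with no peak 6 fell and 6 rose, with a median of -0.03. Grin2b and Grin2a, each with several peaks, were among the falls, as were the neurotrophin receptor gene Ntrk3, from 52.8 to 20.4 FPKM with 3 peaks in each genotype, and the potassium channel gene Kcnma1. The unmarked FMRP-bound genes also lay under random lists matched on level (percentile 0.01), or on level and locus span (percentile 1.76). Level-matched lists had medians of 0.14 for the marked and 0.30 for the unmarked genes, so the raw medians overstate their contrast. Marked genes had medians of 34.2 FPKM and 132 kb of locus span, and unmarked genes 160 FPKM and 48.7 kb. Genes with a peak in 1 genotype were in neither part, and the difference between the marked and unmarked parts was not tested. In 65 of the marked genes, control tags in peak windows were lower in KO by a median log2 difference of -0.26, or -0.11 without WT replicate 2 (single differences from -0.52 to -0.01).

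The change also followed the length of the genomic locus. Among genes in the group with the shortest loci, of 10 groups by locus span, up to 4.65 kb, 211 rose and 54 fell, with a median log2 change of 0.19. Among those in the group with the longest, from 152 kb, 27 rose and 238 fell, with a median of -0.17 (Spearman's rho over 12971 genes -0.253, across genes, which are not independent replicates). Expression level showed the opposite trend (rho 0.229). The FMRP-bound m6A-marked genes have long loci, with a median of 132 kb against 26.5 kb in all genes. With matching on level and locus span, chosen after the trend was seen, random lists had a median of -0.03 (range of 95% -0.126 to 0.0815) against -0.43 in these genes, and 0.09 against -0.04 for all m6A-marked genes. In 9 of the 10 groups of locus span m6A-marked genes had a lower median than unmarked genes.

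**Figure D3:**
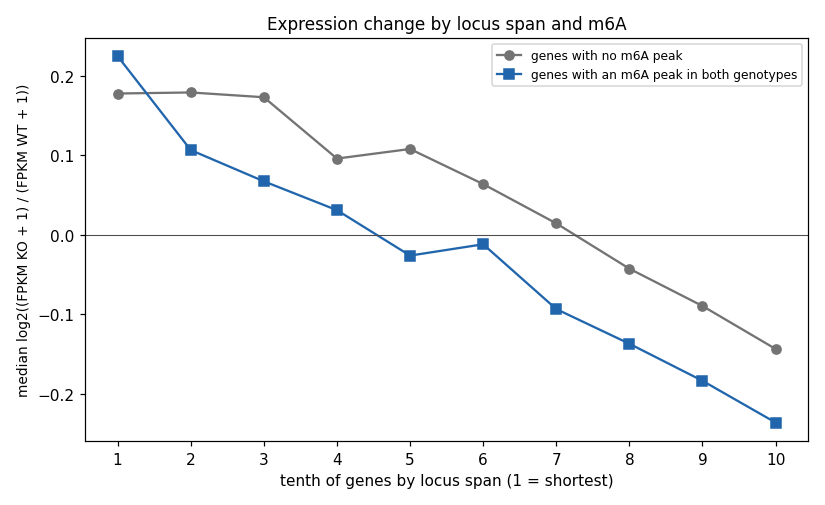
Median log2((FPKM in KO + 1)/(FPKM in WT + 1)) in 10 groups of genes of increasing locus span, for genes with an m6A peak in both genotypes (blue squares) and with no peak (grey circles). Both lines descend, and the m6A-marked genes lie lower in 9 of the 10 groups, the exception being the shortest, at 0.22 against 0.18.

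Changes in methylation and in expression were nearly unrelated across genes. Over 5840 genes Pearson's r between the mean deposited log2 methylation change and the log2 expression change was 0.0409 and Spearman's rho 0.0421, across genes, which are not independent replicates. The libraries behind the methylation table are not given in the sources used here. Non-IP libraries shared with the expression table can by themselves produce a negative relation, or hide a positive one. Of 11 expressed genes with a called site, 3 were called in expression, against 900 of 5829 others (odds ratio 2.05, Fisher's exact test, p = 0.393). Dido1 was lower in methylation and fell from 23.7 to 14.9 FPKM, Ankrd12 was higher in methylation and fell from 13.1 to 7.08 FPKM, and Sdhaf2 was higher in methylation and rose from 5.96 to 9.68 FPKM, per the authors' deposited table.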

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

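The alternatives were fixed before the data were examined, apart from matching on locus span, own loci, m6A peaks taken from the KO list, and lists without FMRP-bound members, which were chosen after seeing the data. No paired analysis was possible because the expression and differential methylation tables behind the tests hold no values per library, and leaving out a replicate was for the same reason limited to results that use the HOMER lists. A replicate block was not run either. A locus of their own was held by 78.4% of all, 79.0% of m6A-marked and 67.3% of FMRP-bound genes. Restricted to such genes, 3023 m6A-marked genes had a median of -0.04 against 0.10 in random lists matched on level and locus span, below every random list. This restriction was not run for the FMRP-bound genes. Matching on transcript length was not run, since no lengths were used here. The fall of m6A-marked genes against matched genes kept its direction and side of the threshold under the alternatives of filter, pseudocount, peak list and matching, with values from -0.18 to -0.10, and so did that of FMRP-bound m6A-marked genes, from -0.61 to -0.40. The alternatives that used HOMER peaks counted only genes with a MeTPeak peak in either genotype, so they are not a check apart from MeTPeak. Leaving out a replicate changed only which genes counted as marked, since the FPKM values stayed pooled over both replicates, so those rows say nothing of whether the fall rests on 1 library. The control tags, which do leave a library out, gave -0.11 without WT replicate 2 against -0.26 for the FMRP-bound m6A-marked genes. Of 108 values for single lists under alternatives, 94 kept their direction and side of the threshold, 4 lost a call (microglia and excitatory markers with span matching, vessels at 5 FPKM, red cells with no filter), 1 gained one (choroid plexus with no filter), and 9 turned, all of lists within the random range in either setting. With span matching these were GABA signalling (0.145), immediate early genes (-0.0998), oligodendrocyte precursors (0.00743), mTOR and translation (0.0297) and thalamic and hypothalamic markers (0.0420). The last were at 0.0221 with no filter and 0.00271 with a pseudocount of 0.1, and without FMRP-bound members GABA signalling was at 0.00713 and mTOR and translation at 0.00524. Centring and recomputed Benjamini-Hochberg values say nothing of stability, since calls rest on the deposited q-values. The depth of the non-IP libraries behind FPKM is unknown, which limits what can be said of low genes.

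With q 0.01 the calls were 478 genes higher and 582 lower and 388 isoforms higher and 484 lower, and with q 0.1 isoforms higher numbered 1195. Methylation calls were 1 higher and 1 lower at FDR 0.01, 24 and 8 at FDR 0.1, and 5 and 1 at an absolute log2 change of 1. Sites lower in KO numbered 1 among genes at 1 FPKM in both genotypes, 1 among HOMER-backed sites, and 1 with any replicate left out of the backing. With a reciprocal overlap of 0.5, 73.2% of WT and 50.8% of KO peaks were shared, and with peaks at FDR 0.01, 55.9% of KO peaks. Replicate-backed WT peaks at a fold of 4 or more numbered 46. Leaving out each replicate gave from 133 to 177 replicate-backed peaks in WT and from 131 to 427 in KO, by construction more, since fewer lists must match. It moved the difference in Jaccard index within minus between genotypes from -0.0429 (without KO replicate 1) to 0.0691 (without KO replicate 2), and that of the shared share of the smaller list from -15.8 (without KO replicate 1) to 16.1 percentage points (without WT replicate 1), against 4.26 with all libraries. Between sites called at FDR 0.05 alone, Spearman's rho of methylation and expression was -0.0727 over 11 genes. Apart from stricter and looser thresholds and the replicate-backed counts, the cause was not tested.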

Other observations

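The tests of the level and span trend, of single libraries, of genes with a peak in 1 genotype and of other cell types were chosen after the results were seen, whereas those of nuclear RNA, of peaks from the KO list and of a second striatal list were written down before their values were looked at. In a first run of both second lists 3 planned genes, Spock3, Nexn and Firre, had been left out by mistake, and they were restored afterwards, with the same outcome of both tests. Several nuclear noncoding RNAs were lower in KO. In a list of 16 such RNAs that left out those already seen, 11 were expressed, of which 6 fell and none rose, with a median log2 change of -0.70, below all 10000 random lists matched on level and locus span. Miat fell from 308 to 105 FPKM, Neat1 from 102 to 39.0, Firre from 32.9 to 14.7, Snhg11 from 599 to 312, Ftx from 10.3 to 5.59 and Rian from 187 to 126, per the authors' deposited table. Malat1, at 1897 and 422 FPKM, and Meg3, at 1723 and 489, were not called in the authors' deposited table (q = 0.0845 and 0.0848). Neither was Lars2, a protein-coding gene, at 5182 and 1413 FPKM (q = 0.338 in the authors' deposited table). Actb rose from 287 to 728 and Gapdh from 428 to 673 FPKM in the authors' deposited table. Malat1, Meg3, Lars2, Actb and Gapdh were chosen after their values were seen. The noncoding RNAs were not examined by library, so a fall carried by a single pool is not excluded.

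Genes with long loci were lower and abundant genes with short loci higher in KO. If 1 library had set this trend, the other 3 would lie on the other side, and they did not. In 4666 windows found in all 4 HOMER lists with an overlap of 80%, of which 3563 lay in peaks of 2469 genes, deviations of the scaled control tags increased with locus span in both WT libraries (Spearman's rho across genes, which are not independent, 0.142 and 0.185) and decreased in both KO libraries (-0.237 and -0.105). Less nuclear RNA in the KO libraries may be a candidate explanation, since the second noncoding list lay at -0.70, but a difference in RNA preparation and an effect of the genotype remain open, as both would be shared by the KO pools. These windows were selected by peak calling and the control libraries are not identified, so they describe peaks in well-expressed genes. Deviations were taken from each gene's mean over the 4 libraries, so they are not independent, and a trend carried mostly by 1 library of each genotype is not excluded. They also followed expression level (rho -0.135 and -0.171 in WT replicates 1 and 2, 0.113 and 0.217 in KO replicates 1 and 2).

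The fall of m6A-marked and FMRP-bound genes was not removed by the trend over level and span, since FMRP-bound m6A-marked genes stayed -0.40 below genes matched on both. Peaks called more easily where WT levels were high are argued against as the whole source, since genes of the KO list, chosen without regard to the WT list, lay -0.11 below matched genes with no peak. They stay open as a part of it. The KO list shares 3829 of its 5479 genes with the m6A-marked set, and genes with a peak in WT alone lay -0.21 below and those with a peak in KO alone 0.03 above matched genes, as peak calling that follows the level of a gene would give. A single library may account for much of it. In 65 of these genes the median log2 difference of control tags, KO minus WT, was -0.26 with all libraries and -0.11 without WT replicate 2, whereas it was -0.47 without WT replicate 1, -0.18 without KO replicate 1 and -0.31 without KO replicate 2. Transcript length, nuclear RNA and the loss of FMRP stay open, and stability was not measured.

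Striatal markers were higher in KO. More striatal tissue in the KO pools may be the source, a hypothesis for which a second list of 19 striatal genes, 15 of them expressed, gave a median of 0.63, above all 10000 random lists, with 7 rises and no fall. Its other expressed genes were not called. Of these, Arpp21, at 161 and 152 FPKM, Foxp1, at 16.9 and 14.6, and Meis2, at 32.3 and 32.4, were lower or nearly level, and the rest were higher. Of the 15 genes of the original list 14 were at 1 FPKM or more in WT cortex and none was in another list, and its most abundant were Ppp1r1b, from 120 to 217 FPKM, Penk, from 72.8 to 234, and Adcy5, at 69.2 and 89.5 and not called, in the authors' deposited table. A lower share of cortical neurons, raising all other cell types alike, is argued against by the marker lists of glia, vessels, meninges, hippocampus, and thalamus and hypothalamus. Their highest upper 95% bootstrap bound, from resampling genes and not pools, was 0.58 against a striatal median of 0.96. The choroid plexus list (3 expressed genes, median 0.40, Ttr at 1.02) and the red cell list (2 expressed genes, median 2.48) were not compared. The argument therefore covers only the lists named. A change of the striatal genes in neurons of KO mice stays open, as dissection and genotype cannot be separated with 2 pools each.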
